A study of Homo sapiens with 24 samples.

How the data were processed

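The data were 24 Agilent Whole Human Genome 4x44K arrays hybridised with 1 colour (Cy3), from the lung cancer lines H23 and H460 and the ovarian cancer lines OVCAR3 and A2780. Per the labels, each line was present as cisplatin-sensitive cells, cisplatin-resistant cells and resistant cells treated with 5-aza-2'-deoxycytidine and trichostatin A, with 2 arrays per group and 12 groups. The source label calls the OVCAR3 and A2780 samples lung while their tissue label says ovarian, which was followed, and 1 treated H460 sample has another line name in its source label and was taken as H460 from its title and cell line label. The scanner output gives each spot's intensity, which per the file headers was background-subtracted and detrended with Agilent Feature Extraction 10.7.3.1, without scaling between arrays. The authors also deposited a table of values in log2 units with 41078 rows, whose scale and centring were found from the values, since neither is stated. Each of its columns correlated best with its own array (24 of 24, r of at least 0.995), all columns held the same quantiles, and the median of every column was 7.65, so it was read as quantile-normalized log2 intensity. Its direction needs no sign, since it holds levels of single arrays. The genome build used for probe design plays no part here, and no coordinates are given.

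For the main values, log2 of the processed intensity was taken minus the log2 75th percentile of the array's spots, without control spots. Outlier spots counted for this percentile and were left out of the probe values. Repeated spots of a probe (10 spots each for 264 probes) were averaged, and up to 4 arrays were allowed to be missing per probe. Of 41000 probes 26222 were named through the accession in the design and a RefSeq gene table (assembly GRCh38.p14, used for names alone), 0 had several symbols, 14778 stayed without a symbol, and 17721 symbols were found, 6473 of them with more than 1 probe. Probes well above background on both arrays of at least 1 of the 12 groups were kept (36745), and each gene took its probe with the highest mean over the 24 arrays, which left 28228 genes or unnamed probes, 16976 with a symbol. No probe was saturated. The brighter probes differed between duplicates by a median absolute log2 of 0.137 to 0.182 per group and the dimmer ones by 0.29 to 0.678, so dim genes carry more error. Where a gene was not well above background on any array of 1 group, the fold is given as at least a bound. A gene counted as well above background where any of its probes was, while its fold came from 1 probe. A fold without a bound may therefore rest on a dim probe. The bound sets the mean of the brighter group against the mean, over the arrays of the dim group, of the higher of the gene's own value and the lowest value among probes well above background on that array. Fitted log2 values of such genes are no bounds.

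Tests were made with limma 3.58.1 in R 4.3.3. Within a line, the 12 groups of 24 arrays shared 1 estimate of the spread (12 residual degrees of freedom), and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 change of at least 1. Across lines, duplicates were averaged and the line was a block (6 residual degrees of freedom), with a call at an adjusted p under 0.05. Differences between lines were tested as an interaction over the 24 arrays, and differences between lung and ovarian lines on the averaged values. Gene lists were tested across lines with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, and p-values were adjusted over the 32 lists of a comparison. Between lines, camera set the change of a list in 1 line against the mean change of the other lines. Of the lists after treatment fry called 12 on balance in 1 direction, and for resistance it called 0, with a smallest adjusted p of 0.934. Tests are 2-sided.

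The groups, the tests, the alternatives, the lists and the rule for naming genes were fixed before the data were examined. The rule named, across lines, the 10 highest and 10 lowest mean changes among genes that passed with the same sign in all 4 lines, or the 5 of smallest p per direction where fewer than 5 passed. It also named the 4 highest and 4 lowest called genes per line, up to 4 members per list, the 5 genes of largest summed change that were raised and then lowered (or the reverse) in 2 or more of the same lines, and MAFG, ELK1, ABCA1, MAPKAPK2, HNRNPK and MIR7-3HG. Clone names and a fixed set of sex-linked genes were left unnamed, and some genes that the rule selects are not reported here. The lists were candidate miR-7 targets of the study, host transcripts, published miR-7 targets, platinum transport, glutathione and metallothionein, NRF2 and MAF targets, nucleotide excision repair, Fanconi and homologous recombination, mismatch repair, p53 targets, apoptosis, cell cycle, mesenchymal, epithelial, cancer-testis, interferon response, antigen presentation, inflammatory and NF-kB, DNA methylation and chromatin enzymes, genes raised by histone deacetylase inhibitors, endoplasmic reticulum stress and ATF4, hypoxia and glycolysis, cholesterol synthesis, MAPK output, Wnt targets, stem cell, neuroendocrine and neural, blood, endothelial, fibroblast, lung lineage and ovarian lineage genes. Some genes belong to more than 1 list, among them COL1A2 and COL3A1, which are both mesenchymal and fibroblast genes.

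The alternatives were quantile normalization, the authors' deposited table, the mean of all probes of a gene, a filter for probes well above background on all 24 arrays, no filter on dim probes, normexp background correction (offset 50), leaving out each array or each line, the replicate number as a block, no minimum fold or an added one, a trended and robust variance, the slide as a random or fixed block, and no line block. Normexp was planned on the mean signal, which is not used here, and was run on the median signal instead. The steps were tested on simulated data with 27467 features. Within a line 26.9%, 71.6% and 97.0% of planted changes of log2 1, 2 and 4 were recovered for resistance, and across lines 0%, 41.8% and 89.4% for treatment. Unplanted features called were 7 within a line and 2 across lines. The simulated noise was independent between arrays, while the real arrays of 1 slide had an estimated correlation of 0.459. These rates therefore leave out slide effects, which the real comparisons of conditions include. Other tools were statmod 1.5.0, python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.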

Results

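Gene expression was measured in 4 human cancer cell lines, the lung lines H23 and H460 and the ovarian lines OVCAR3 and A2780. Each line was profiled in 3 conditions. These were cells sensitive to cisplatin (a platinum drug that crosslinks DNA), resistant cells selected under rising cisplatin doses, and resistant cells given a combined treatment. The treatment was 5-aza-2'-deoxycytidine (an inhibitor of DNA methylation) together with trichostatin A (an inhibitor of histone deacetylases). Every one of the 12 groups had 2 arrays, giving 24 1-colour arrays with 41000 probes each. The series concerned miR-7, a microRNA, and platinum resistance. The comparisons asked which transcripts changed when resistance arose and which changed when the resistant cells received the demethylating treatment. The arrays measured messenger and other long RNAs, and miR-7 itself was not analysed here. The 75th percentile of the processed intensity lay between 1472 and 2660 per array, between 69.5% and 86.4% of probes were well above background, and no probe was saturated. Duplicates correlated across probes with r between 0.979 and 0.99, and the number of arrays limits the precision of all values. The labels describe the duplicates as repeat hybridisations, so they may be technical. P-values from fits over the 24 arrays then measure only the spread between hybridisations and their slides, and no spread between cultures. Each of the 6 slides held 1 condition of all 4 lines, so that comparisons of conditions were also comparisons of slides.

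In A2780, acquisition of resistance went with the loss of interferon and antigen presentation transcripts. Of 30 measured interferon response genes 19 fell and 0 rose, and of 24 antigen presentation genes 16 fell and 0 rose. PSMB8, an immunoproteasome subunit, was 94.1-fold lower in resistant cells (log2 -6.56 ± 0.18 SE, n = 2 arrays per group, limma adjusted p = 6.06e-12), and GBP5, an interferon-induced GTPase, was 2170-fold lower (log2 -11.08 ± 0.39, adjusted p = 9.59e-11). IFNG, which encodes interferon gamma, was well above background in sensitive cells and not in resistant ones, a difference of at least 707-fold (adjusted p = 2.94e-10). HLA-DRA, a class II antigen presentation chain, was at least 6.28-fold lower (adjusted p = 1.51e-05). The detoxifying enzyme gene AKR1C3 fell 55.4-fold (log2 -5.79 ± 0.21, well above background on 1 of 2 resistant arrays) and the neuronal enolase gene ENO2 fell 37.7-fold (log2 -5.24 ± 0.16). The drug efflux pump gene ABCG2 fell 13.5-fold (log2 -3.75 ± 0.37) and the mesenchymal cadherin gene CDH2 fell 20.8-fold (log2 -4.38 ± 0.17). The strongest decreases also included the homeobox gene NKX3-2, at least 365-fold, and the serotonin synthesis gene TPH2, at least 457-fold. The strongest increases were in SLC22A15, a solute carrier gene (254-fold, log2 7.99 ± 0.15, well above background on 1 of 2 sensitive arrays), LRRTM1 (159-fold, log2 7.31 ± 0.70), PPIC (116-fold, log2 6.85 ± 0.18) and the kinase gene MARK1 (at least 55.7-fold). Of 23 inflammatory and NF-kB genes 2 rose and 7 fell, and the change of this list lay below the mean of the other lines by a median log2 of -1.53 (camera adjusted p = 9.75e-06, and adjusted p = 0.293 with an estimated correlation). PTGS2, the inducible cyclooxygenase gene, was 1 of the 2 that rose, by 20.6-fold (log2 4.37 ± 0.20, well above background on 1 of 2 sensitive arrays). Among 9 measured fibroblast markers 2 rose and 4 fell in this line, including DCN (31.8-fold lower) and COL1A2 (60.2-fold lower). In total 3660 genes were called at an adjusted p under 0.05 and a fold of at least 2, with 2143 higher and 1517 lower. Without replicate 2 of the A2780 sensitive arrays 1896 were higher and 2429 lower, so the balance of directions rests on that array. Of the 3660 genes, 2772 were measured above background in both groups, 743 in 1 group and 145 in neither.

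In H23, 8 of 30 interferon response genes rose in resistant cells and 1 fell, and epithelial and inflammatory genes changed in both directions. The change of the interferon list lay above the mean of the other lines by a median log2 of 0.84 (camera adjusted p = 1.14e-05, and adjusted p = 0.406 with an estimated correlation). That mean includes the fall in A2780. Medians of the list were 0.685 in H23, 0.057 in H460, 0.843 in OVCAR3 and -1.633 in A2780, so H23 did not lie above OVCAR3. CDH1, the epithelial cadherin gene, was 71.9-fold higher (log2 6.17 ± 0.20, n = 2 arrays per group, limma adjusted p = 2.32e-10), and KRT19, an epithelial keratin gene, was 38.6-fold higher (log2 5.27 ± 0.21). Of 21 measured epithelial genes 6 rose and 3 fell, and of 23 inflammatory and NF-kB genes 7 rose and 4 fell, and neither list differed from the other lines past the threshold (camera adjusted p = 0.403 and 0.33). The chemokine gene CCL2 rose 90.5-fold (log2 6.50 ± 0.50), the homeobox gene MEOX1 48.2-fold and AJAP1, a junction protein gene, 46.8-fold. ICAM1, an adhesion receptor gene induced by NF-kB, rose 13-fold (log2 3.70 ± 0.11), and ACTA2, a smooth muscle actin gene counted among mesenchymal genes, rose 10.1-fold (log2 3.34 ± 0.10). COL3A1, a fibrillar collagen gene, fell 42.2-fold (log2 -5.40 ± 0.20) and LUM, a matrix proteoglycan gene, was at least 57.4-fold lower. These 2 genes belong to the 9 measured fibroblast markers, of which 3 fell and 0 rose. The glutathione transferase gene MGST2 was at least 47.4-fold lower (adjusted p = 8.13e-11), ATP8B4 at least 43.4-fold and PABPC4L at least 46.5-fold. The long noncoding gene CASC15 fell 74.6-fold (log2 -6.22 ± 0.22, well above background on 1 of 2 resistant arrays). In total 3721 genes were called, 1515 higher and 2206 lower.

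In OVCAR3, 8 of 24 antigen presentation genes rose in resistant cells and 0 fell. Among them were genes of class II presentation, of which HLA-DRA rose 41.6-fold (log2 5.38 ± 0.47, n = 2 arrays per group, limma adjusted p = 2.22e-06), HLA-DPA1 rose 35.3-fold (log2 5.14 ± 0.17) and HLA-DMB rose 19.1-fold (log2 4.26 ± 0.16). Of 30 interferon response genes 8 rose and 0 fell. HMOX1, the heme oxygenase gene, rose 7-fold (log2 2.81 ± 0.16), and SPOCK1, a proteoglycan gene, rose 71.0-fold (log2 6.15 ± 0.35). The largest increases were in ABHD12B, at least 53.8-fold, SLC1A6, a glutamate transporter gene, at least 43.3-fold, and CLC, 125-fold (log2 6.96 ± 1.13, well above background on 1 of 2 sensitive arrays). The largest decreases were in LCMT2, at least 87.0-fold, TAFA5, at least 46.7-fold, the zinc finger gene ZNF518B, 130-fold (log2 -7.02 ± 0.13). LAYN, a hyaluronan receptor gene, fell 115-fold (log2 -6.85 ± 0.84, well above background on 1 of 2 resistant arrays). COL1A2 was at least 22.8-fold lower, and it was the 1 gene called among the 9 fibroblast markers. Of 33 measured cancer-testis genes 7 fell and 0 rose. In total 2287 genes were called, 1107 higher and 1180 lower.

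H460 showed the fewest differences between resistant and sensitive cells, with 270 genes called, 114 higher and 156 lower. KRT7, a simple epithelial keratin gene, was at least 40.2-fold lower in resistant cells (n = 2 arrays per group, limma adjusted p = 8.42e-06). SLFN11, which encodes a factor that blocks stressed replication forks, was 12.9-fold lower (log2 -3.69 ± 0.37, adjusted p = 0.00014), CRB1 was 8.78-fold lower (log2 -3.13 ± 0.50) and SERTAD4 8.60-fold lower (log2 -3.10 ± 0.39, well above background on 1 of 2 resistant arrays). DNALI1, an axonemal dynein gene, was 28.5-fold higher (log2 4.83 ± 0.25, well above background on 1 of 2 sensitive arrays), the complement gene C3 was 11.2-fold higher (log2 3.49 ± 0.17), SIGLEC11 was 8.59-fold higher and the gap junction gene GJA5 was 8.07-fold higher. Of 23 inflammatory and NF-kB genes 7 rose and 0 fell, while 0 of 30 interferon response and 0 of 24 antigen presentation genes were called. Of the 9 fibroblast markers 2 fell, including DCN (4.96-fold lower). The count rose to 580 without replicate 2 of the H460 sensitive arrays. When the same 4 slides were grouped so that sensitive and resistant arrays balanced, 2430 and 2642 genes differed 2-fold in H460, more than the 1435 of the real grouping. The differences of this line could not be told apart from slide effects. In the other lines the real grouping gave more (5167 against at most 1891 in H23, 3533 against at most 1591 in OVCAR3, and 5101 against at most 2462 in A2780). The regroupings cannot show a difference common to both slides of a condition, so slide effects stay open in those lines too.

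The series asked whether the 4 lines shared a change on becoming resistant. C3 rose in 4 of 4 lines, by 2.44-fold in H23, 11.2-fold in H460, 2.26-fold in OVCAR3 and 3.02-fold in A2780, but its mean over lines did not pass (log2 1.89 ± 0.63, n = 4 lines, limma adjusted p = 1). CH25H, which encodes cholesterol 25-hydroxylase, was also called higher in 4 lines (mean log2 2.30), and EFR3B, NOL4, TEX12 and TMPRSS15 were called lower in 4 lines (mean log2 -1.59, -1.98, -1.22 and -2.28). The naming rule picked C3 by its change in H460, and the other genes were chosen after their values were seen, so all were selected on these data. The heme oxygenase gene HMOX1 rose in H23 (2.70-fold), H460 (3.24-fold) and OVCAR3 (7-fold), and its value in A2780 was 1.28-fold (limma adjusted p = 0.118). Of 31 glutathione and metallothionein genes 9, 3, 5 and 6 rose and 2, 0, 0 and 1 fell in H23, H460, OVCAR3 and A2780, and MT1L, a metallothionein gene, was 3.05-fold higher in H23 and 2.40-fold higher in H460. Across the 4 lines limma called 0 of 28228 genes, with 833 genes at an unadjusted p under 0.05, a smallest adjusted p of 1, and 0 calls with a trended and robust variance. With the slide as a random block over the 24 arrays, a fit that leaves out the spread between lines, 2283 genes passed, and arrays of number 1 alone gave 661 and of number 2 alone 487. The genes with the smallest p were G6PC2, CXCR5, APOA4, GABRR3 and ADGRF3 among those higher, with mean log2 between 0.99 and 1.05. Among those lower they were DSC3, LRTM2, CNTNAP4, KCNJ8 and NSG1, with mean log2 between -3.09 and -1.59, and none passed in either direction. In 3 or more lines 97 genes were called in the same direction (37 higher and 60 lower, where independent lists would give 5.5 and 6.4). The real grouping of slides gave 105 genes 2-fold higher and 139 2-fold lower in 3 or more lines, and the 2 balanced groupings of the same slides gave 724 and 743 higher and 11 and 127 lower. The sign of a balanced grouping is arbitrary, so its directions may be exchanged. The shared calls could not be separated from slide effects.

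No member of the 32 gene lists passed across lines for resistance, and 0 passed when adjusted over the list alone. The competitive camera test called 6 lists across the 4 lines. Glutathione and metallothionein genes were shifted up (31 measured, median log2 0.27, adjusted p = 0.0202), as were genes known to rise under histone deacetylase inhibitors (18 measured, median log2 0.34, adjusted p = 0.008). The glutathione and metallothionein shift had an adjusted p of 0.0611 in the authors' deposited table. Cholesterol synthesis (22 measured, median log2 -0.24, adjusted p = 0.00696), Fanconi and homologous recombination (26 measured, median log2 -0.16, adjusted p = 0.00696), cell cycle (33 measured, median log2 -0.11, adjusted p = 0.0366) and fibroblast marker genes (9 measured, median log2 -0.41, or -0.61 with dim values at the background limit, adjusted p = 0.008) were shifted down. With an estimated correlation none of the 6 held, with adjusted p = 0.912 for the cell cycle list and adjusted p = 0.648 for each of the others. The cell cycle call also ended without a filter on dim probes (adjusted p = 0.0841). For the other 26 lists the adjusted p lay between 0.144 and 0.927. For published miR-7 targets, cancer-testis, antigen presentation, endoplasmic reticulum stress, Wnt target and lung lineage genes, the median, the mean and the direction of the test differed in sign.

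Among transcripts tied to miR-7, MIR7-3HG, the host transcript of a miR-7 gene, fell in resistant A2780 cells by 21.4-fold (log2 -4.42 ± 0.75, n = 2 arrays per group, limma adjusted p = 0.000485). After treatment it was 201-fold higher in A2780 (log2 7.65 ± 0.75, adjusted p = 7.9e-07), 95.2-fold higher in H23 (log2 6.57, adjusted p = 4.22e-06) and 35.1-fold higher in OVCAR3 (log2 5.13, adjusted p = 8.79e-05). In H460 its log2 change was -0.02 (adjusted p = 0.988). Over the 4 lines the mean change after treatment was log2 4.83 ± 1.28 with an adjusted p of 0.0518, which became 0.0491 with quantile scaling, 0.0496 in the authors' deposited table and 0.0499 with probes of a gene averaged. HNRNPK, whose intron holds another miR-7 gene, fell in treated H23 (log2 -1.08 ± 0.09, adjusted p = 1.28e-07), and its mean over lines was log2 -0.48 ± 0.22 (adjusted p = 0.188). Of the 2 host transcripts 0 passed across lines over all genes, and 1 rose after treatment when adjusted over the list alone (camera adjusted p = 0.893). ABCA1, a cholesterol efflux transporter gene and 1 of 4 candidate miR-7 targets named by the study, rose in resistant H23 (log2 1.01 ± 0.22) and A2780 (log2 1.32 ± 0.22). After treatment it fell in H23 (log2 -2.08), OVCAR3 (log2 -2.03) and A2780 (log2 -1.15). MAFG, a small MAF transcription factor gene, fell after treatment in H23 (log2 -1.31 ± 0.18) and A2780 (log2 -1.15 ± 0.18), with values of -0.95 in H460 and 0.64 in OVCAR3 that were under 2-fold. ELK1 and MAPKAPK2, a transcription factor and a kinase gene of the MAPK pathway, had mean changes after treatment of log2 -0.51 ± 0.22 and -0.07 ± 0.26 (adjusted p = 0.168 and 0.887), and the sign of MAPKAPK2 turned with quantile scaling. Of the 4 candidates 0 passed across lines in either comparison, also when adjusted over the list alone. Their median after treatment was log2 -0.60 (camera adjusted p = 0.112, fry adjusted p = 0.0469), and since the study chose them on these samples, the list is not independent evidence of its direction. Of 25 published miR-7 targets 0 passed, with a median of log2 -0.05 after treatment (camera adjusted p = 0.607).

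**Figure D1:**
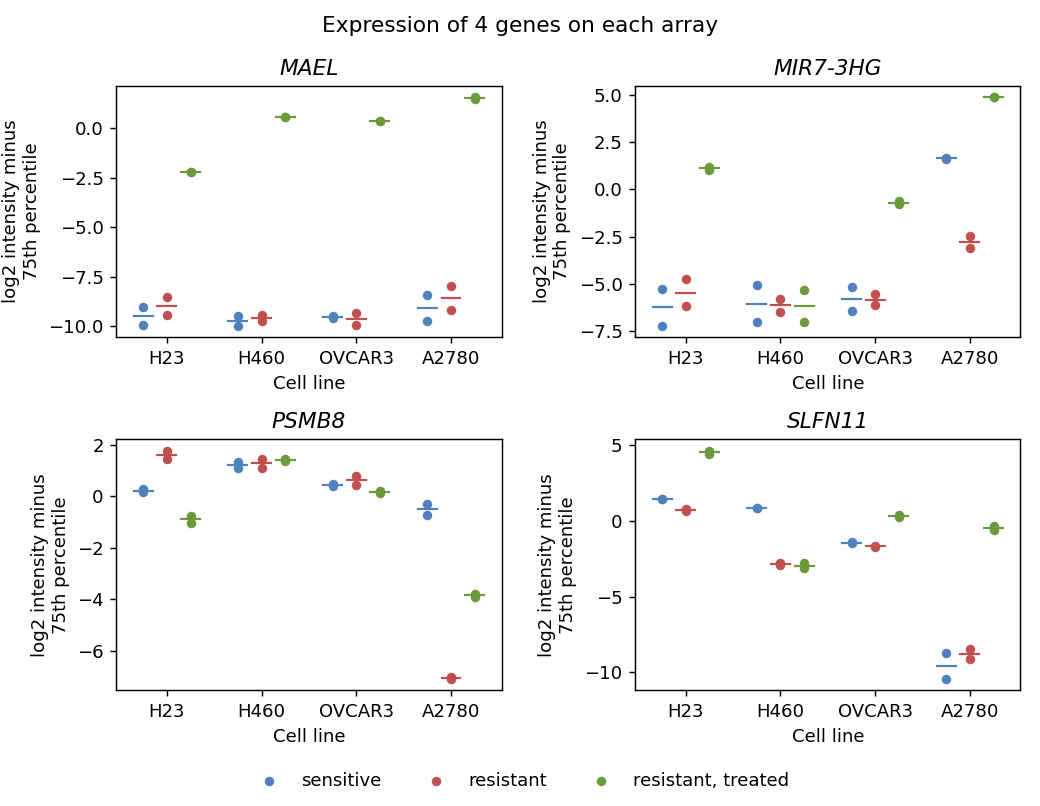
Log2 intensity minus the 75th percentile of its array for MAEL, MIR7-3HG, PSMB8 and SLFN11 in sensitive, resistant and treated resistant cells of the 4 lines, with each array as a point and the mean of 2 arrays as a line. MIR7-3HG in A2780 lay at 1.67 and 1.58 in sensitive, -3.08 and -2.50 in resistant and 4.86 and 4.86 in treated cells.

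The second comparison asked what the combined treatment changed in resistant cells, and most of the measured cancer-testis genes rose. Of 49 listed cancer-testis genes, which are normally confined to the germline, 33 were measured. Of these, 24 rose across lines and 0 fell (31 when adjusted over the list alone), with a median log2 of 5.91, or 5.30 with dim values set to the background limit. A gene silent in untreated cells counted as measured only if treated cells expressed it. The share raised and the median of this and other lists are therefore biased towards rises. The camera adjusted p was 4.45e-20, and the adjusted p was 0.263 with an estimated correlation. In H23, 24 of the 33 rose and 1 fell, and their change lay below the mean of the other lines by a median log2 of -3.64 (camera adjusted p = 6.73e-10, and adjusted p = 0.291 with an estimated correlation, or 0.0458 with that and the slide as a fixed block). MAEL, a germline transposon silencing gene, rose by at least 29.8-fold in H23, at least 295-fold in H460, at least 289-fold in OVCAR3 and at least 790-fold in A2780 (fitted mean log2 9.27 ± 0.58, n = 4 lines, limma adjusted p = 0.000375). RHOXF2B, a reproductive homeobox gene, rose by at least 26.6-fold in H23 and at least 2650-fold in H460 (fitted mean log2 10.79 ± 0.98, adjusted p = 0.00132), and FMR1NB by at least 234-fold in H23 and at least 940-fold in H460 (fitted mean log2 9.72 ± 0.44, adjusted p = 0.000297). The other genes with the largest mean increases were TRIM43, DDX43, RHOXF2, VCX2, SYCP3, VCX and DMRTB1, with fitted mean log2 between 8.99 and 10.16. Members of the RHOXF2 and VCX families are near-identical copies, so their probes may not separate them. Markers of other cell types also rose across lines, with 6 of 15 blood markers, 5 of 11 endothelial markers and 8 of 19 neuroendocrine and neural genes, while 0 fell. When adjusted over the list alone, 11 blood markers rose and 1 fell, 7 endothelial markers rose, and 12 neuroendocrine and neural genes rose. Among them were HBA1, a hemoglobin gene (45.2-fold on average, log2 5.50 ± 0.55, adjusted p = 0.00199), CSF1R, a macrophage receptor gene (28.3-fold), the endothelial adhesion gene PECAM1 (fitted log2 6.05 ± 0.59), the neurofilament gene NEFM (237-fold, log2 7.89 ± 1.03) and the neuronal gene STMN2 (fitted log2 5.78 ± 0.36). Camera gave adjusted p = 2.53e-05 for blood markers, 2.53e-05 for neuroendocrine and neural genes and 0.000202 for endothelial markers, and with an estimated correlation the adjusted p was 0.0574, 0.0574 and 0.158. Their medians were log2 2.78, 1.79 and 2.12, and 2.17, 1.51 and 1.65 with dim values at the background limit.

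Some inflammatory genes and some genes known to rise under histone deacetylase inhibitors rose as well. Of 23 inflammatory and NF-kB genes 5 rose and 0 fell (9 when adjusted over the list alone), including the cytokine gene TNF (log2 3.07 ± 0.54, n = 4 lines, limma adjusted p = 0.015), the chemokine gene CCL20 (log2 4.45 ± 0.92), CSF3, a granulocyte growth factor gene (fitted log2 6.51 ± 1.16), and the apoptosis inhibitor gene BIRC3 (10.4-fold, log2 3.37 ± 0.74). The camera adjusted p was 0.000202 and the adjusted p was 0.325 with an estimated correlation. Of 18 genes known to rise under histone deacetylase inhibitors 6 rose and 0 fell, led by the dehydrogenase gene DHRS2 (53.9-fold, log2 5.75 ± 0.81, adjusted p = 0.00726), with camera adjusted p = 0.0427 and adjusted p = 0.384 with an estimated correlation. Of 12 Wnt targets 1 rose, TCF7 (log2 1.61 ± 0.33), and 6 rose when adjusted over the list alone (camera adjusted p = 0.0141, adjusted p = 0.314 with an estimated correlation). Of 21 epithelial genes 1 rose, the transcription factor gene OVOL1 (log2 4.17 ± 1.01), and 3 when adjusted over the list alone (camera adjusted p = 0.00402, adjusted p = 0.672 with an estimated correlation), with medians of 3.95 in A2780 and -0.43 in OVCAR3. The immediate early gene FOS rose 9.87-fold (log2 3.30 ± 0.31, adjusted p = 0.00161), the cell cycle inhibitor gene CDKN1A 2.75-fold (log2 1.46 ± 0.28, adjusted p = 0.0201) and OASL, an interferon-induced gene, 9.37-fold (log2 3.23 ± 0.63, adjusted p = 0.0212). The stress response gene NUPR1 fell 7.44-fold (log2 -2.90 ± 0.64, adjusted p = 0.0306), and TESMIN, CC2D2A, RBMS3, COX19, SENP6, ORAI3, SLC35E2B and MORN4 had mean log2 between -2.24 and -1.95. SENP6 was well above background on 1 of 2 treated arrays in each line, with an SE within a line of 1.60. With normexp background correction fitted without spots far under their background, NUPR1 no longer passed (adjusted p = 0.0524), and a fit on all spots, which a few such spots distorted, ended the calls of all the genes named here among the lowest (0.111 for NUPR1). Of 19 endoplasmic reticulum stress and ATF4 genes 3 fell and 0 rose (3 and 1 when adjusted over the list alone), namely DDIT4, an inhibitor of mTORC1 signalling, SHMT2, a serine metabolism enzyme, and XBP1, a transcription factor of the unfolded protein response (log2 -1.56 ± 0.34, -1.09 ± 0.24 and -0.99 ± 0.21). The lines went opposite ways, with 7 up and 2 down in H23 (median log2 0.80), 0 up and 11 down in H460 (-1.40), 2 up and 0 down in OVCAR3 (0.24) and 0 up and 10 down in A2780 (-1.16). This list had camera adjusted p = 0.0179 and adjusted p = 0.672 with an estimated correlation. Its call ended with quantile scaling (0.497), in the authors' deposited table (0.494) and with a strict filter (0.13).

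Across the 4 lines few drug transport and repair genes passed. ABCB1, which encodes the P-glycoprotein drug efflux pump, rose by at least 119-fold in H23, at least 18-fold in OVCAR3 and at least 26.9-fold in A2780, with log2 0.23 in H460 (fitted mean log2 4.83 ± 1.16, n = 4 lines, limma adjusted p = 0.0386). It was the 1 gene to pass of 16 platinum transport genes (camera adjusted p = 0.576), while within H23, H460, OVCAR3 and A2780 4, 1, 4 and 6 of them rose and 2, 4, 1 and 2 fell. Fry's test for change in either direction gave adjusted p = 0.00565 for platinum transport, 0.000401 for Fanconi and homologous recombination, 4.96e-05 for mismatch repair and 0.00645 for nucleotide excision repair. Most other lists passed it too, among them blood (4e-06), endothelial (3.58e-05) and lung lineage markers (0.00341). Candidate miR-7 targets, host transcripts, NRF2 and MAF targets, cell cycle, epithelial, antigen presentation and ovarian lineage genes did not. Passing this either-direction test therefore does not single out transport or repair. Of 8 mismatch repair genes 0 passed across lines (camera adjusted p = 0.806). Of 31 glutathione and metallothionein genes 8 rose and 2 fell (12 and 3 when adjusted over the list alone, camera adjusted p = 0.15), and the metallothionein genes MT1M, MT3, MT1E and MT1G had log2 5.81 ± 0.94, 3.14 ± 0.54, 2.62 ± 0.60 and 2.33 ± 0.51. FANCB was the 1 of 26 Fanconi and homologous recombination genes to rise (log2 1.11 ± 0.20, camera adjusted p = 0.834), and 0 of 23 nucleotide excision repair genes passed (0.15). Of 25 p53 targets CDKN1A, PLK3 and TIGAR rose and CCNG1 fell (camera adjusted p = 0.672), and of 30 apoptosis genes BIRC3 and BIK rose (0.414). Of 22 cholesterol synthesis genes 2 rose, among them STARD4, a sterol transporter gene, and SREBF2 fell (0.679). No gene passed among 22 NRF2 and MAF targets (0.591), 33 cell cycle genes (0.295), 24 antigen presentation genes (0.806) or 13 stem cell markers (0.15). Within lines the cell cycle genes differed, with 2 up and 7 down in H23, 13 and 0 in H460, 6 and 0 in OVCAR3 and 4 and 3 in A2780. Of 23 mesenchymal genes 3 rose, COL1A2, SNAI1 and COL5A1 (5 over the list alone, 0.0579), of 30 interferon genes 3 (4 over the list alone, 0.15), of 19 MAPK output genes FOS (4 over the list alone, 0.15), and of 9 fibroblast markers COL1A2 (2 over the list alone, 0.112). In the lists of 27 DNA methylation and chromatin enzymes, DNMT3L rose and HDAC4 fell (0.414), and of 22 hypoxia and glycolysis genes ANKRD37 rose (0.979). TP63, of 10 lung lineage markers, and FOLR1, of 9 ovarian lineage markers, each rose (0.607 and 0.576). The counts over the list alone equalled those over all genes where none is given. Fry's test for change in 1 direction gave adjusted p = 0.041 for p53 targets, 0.0301 for glutathione and metallothionein, 0.0365 for mesenchymal genes and 0.0113 for stem cell markers, all higher. Of the other lists named in this paragraph it called blood (adjusted p = 0.000362) and endothelial markers (0.00136) as higher and candidate miR-7 targets (0.0469) as lower, and none of the rest. For published miR-7 targets, NRF2 and MAF targets, mismatch repair, apoptosis and cholesterol synthesis, the median, the mean and the direction of the test differed in sign.

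**Figure D2:**
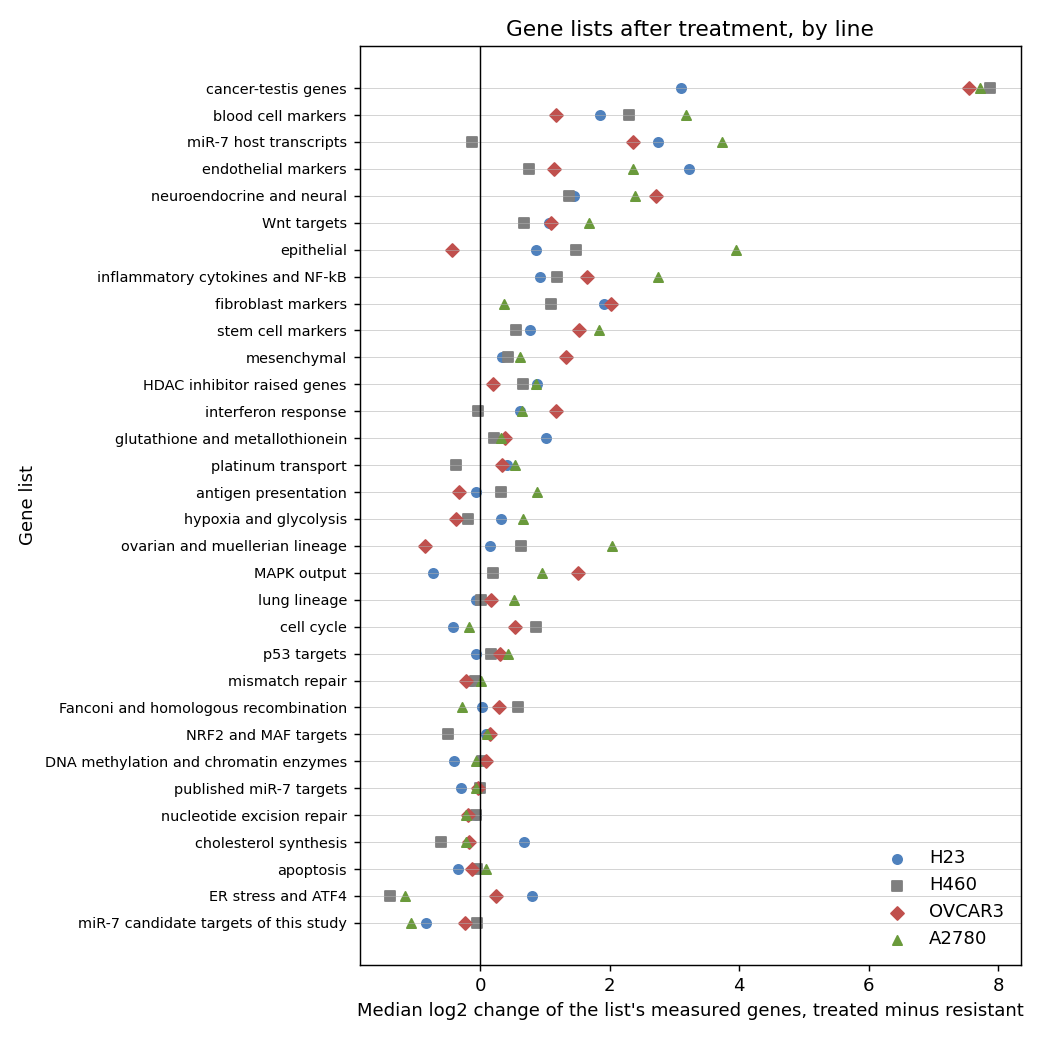
Median log2 change between treated and untreated resistant cells of the measured genes of each of 32 lists, drawn for each of the 4 lines. Cancer-testis genes lay at 3.1 in H23, 7.88 in H460, 7.56 in OVCAR3 and 7.72 in A2780.

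In each line more genes were called for the treatment than for resistance. For H23, 9027 genes were called, 5756 of them higher, led by ANKRD1, a cardiac ankyrin repeat gene (at least 1100-fold, limma adjusted p = 2.81e-11, n = 2 arrays per group), TAC1, a tachykinin gene (at least 444-fold), and the defensin gene DEFB103B (at least 362-fold). GALNT15 (at least 11-fold), APOL6 (40.6-fold), PDE4B (35.8-fold) and IGF2BP1 (27.3-fold) fell most there. For H460, 5183 genes were called, 3521 higher, led by RHOXF2B, TRIM43, MAGEA4 (at least 2940-fold) and GRM5P1 (at least 1090-fold), and with PRDM16 (at least 27.6-fold), GABRG1 (at least 32.5-fold), DSTN and ITPKC lowest, where the last pair had SE of 2.05 and 1.84. For OVCAR3, 5485 genes were called, 3927 higher, led by RHOXF2B, the germ cell gene DAZL (at least 546-fold), L1TD1 (at least 499-fold) and FBP2 (at least 409-fold), and with SLC26A7, RHEX, LGR5 and ESRRG lowest (20, 15, 14.9 and 14-fold). For A2780, 9775 genes were called, 6592 higher, led by DDX43 (at least 2020-fold), VCX2 (5040-fold), ARL14 (at least 1280-fold) and VCX3A (4510-fold), and with MFAP4, IL20RB, CA14 and the transcription factor gene ATF5 lowest (36.7, 21.4, 19.5 and 19.5-fold). The share of higher calls was 63.8% in H23, 67.9% in H460, 71.6% in OVCAR3 and 67.4% in A2780, and became 53.4%, 56.4%, 55.5% and 49.1% with quantile scaling and 53.3%, 56.3%, 55.3% and 49.3% in the authors' deposited table. In 3 or more lines 3236 genes were called the same way, 2704 higher and 532 lower (83.6% higher, and 63.6% in both other scalings), where independent lists would give 499 and 59.5, and 922 rose and 64 fell in all 4 lines. Across lines 2708 genes passed, 1892 higher and 816 lower (69.9% higher, and 36.4% with quantile scaling and 36.6% in the authors' deposited table). Among genes well above background on all 24 arrays, which leaves out those silent in any group, 624 were higher and 841 lower across lines (42.6% higher), and the share higher was 49.2%, 55.6%, 60.4% and 50.8% in H23, H460, OVCAR3 and A2780 and 65.9% for calls in 3 or more lines. The median log2 change of all genes was 0.06, 0.02, 0.04 and 0.14 in H23, H460, OVCAR3 and A2780, and -0.15, -0.12, -0.14 and -0.23 with quantile scaling, so changes near these sizes have no settled direction. Without replicate 1 of treated OVCAR3, of resistant A2780 or of treated A2780, the genes lower across lines were 532, 537 or 536. With the slide as a random block, 13438 genes passed across lines, and without H23, H460, OVCAR3 or A2780 the count was 1091, 1105, 749 or 699. The real grouping of the slides gave 3384 genes 2-fold higher and 695 2-fold lower in 3 or more lines. The balanced regroupings gave 128 and 14 higher and 6 and 758 lower. Their sign is arbitrary, so 758 bears on both directions, and the shared decreases could not be told apart from slide effects.

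**Figure D3:**
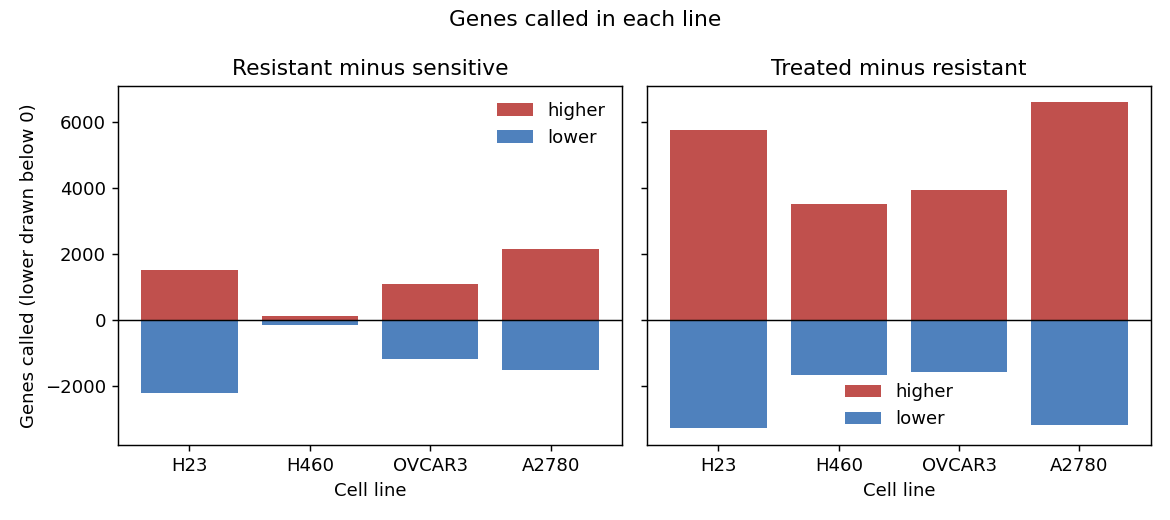
Number of genes called higher (above 0) and lower (drawn below 0) in each of the 4 lines, for resistant against sensitive and for treated against untreated resistant cells. Calls after treatment ranged from 5183 in H460 to 9775 in A2780, and calls for resistance from 270 in H460 to 3721 in H23.

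Genes lowered in resistant cells were often raised by the treatment. Of the genes lowered in resistance, 1032 of 2206 rose after treatment in H23, 105 of 156 in H460, 584 of 1180 in OVCAR3 and 997 of 1517 in A2780, where independent lists would share 449.8, 19.5, 164.2 and 354.3. Examples in several lines were KCNJ8, a potassium channel gene (resistance log2 -4.07 ± 0.32 in H23, and at least 9.86-fold lower in OVCAR3 and at least 2.26-fold lower in A2780), LAYN (log2 -9.43 ± 0.84 in A2780), and GRM5P1, TRIM53AP and TRIM49 (log2 -5.93, -5.52 and -5.33 in A2780). Of the genes raised in resistance, 419 of 1515, 16 of 114, 198 of 1107 and 489 of 2143 fell after treatment (independent lists would share 175.6, 6.7, 61.1 and 241.7), among them SPOCK1, ZFHX4-AS1, KCNMA1, ALPK1 and SLFNL1. Further increases after treatment were seen in 287, 42, 254 and 695 of the raised genes (308.9, 14.2, 154 and 500.5 for independent lists). Both comparisons used the same resistant arrays, which adds a negative covariance without any effect. Across genes the covariance of the changes was -0.315 in H23, -0.132 in H460, -0.230 in OVCAR3 and -0.559 in A2780, against -0.118, -0.121, -0.120 and -0.118 in 20 simulations of unchanged groups sharing those arrays, so the difference was -0.197, -0.011, -0.110 and -0.441. The correlations across genes, which are not independent replicates, were -0.243, -0.208, -0.212 and -0.287, and the simulated ones -0.496, -0.503, -0.500 and -0.495. With 1 resistant array for each comparison the covariance was -0.2 in H23, -0.029 in H460, -0.148 in OVCAR3 and -0.47 in A2780, and with no shared slide number either it was -0.089, 0.091, -0.036 and -0.372. Unchanged groups, simulated without slide effects, gave at most 0.05 such genes per simulation. The counts of genes were not split by array, and part of their excess may come from the shared arrays.

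The lines were also compared with each other. For resistance, limma found 12400 genes whose change differed between the 4 lines, and 17350 with the slide as a fixed block, which this comparison allows since each slide held all lines. For treatment the counts were 17262 and 21156. These tests take arrays as replicates, so with technical duplicates a difference between single cultures would count as one between lines. CDH1 is an example, with resistance changes of log2 6.17 in H23 and -0.41 in OVCAR3, and ICAM1 another, with log2 3.70 in H23 and -3.20 in A2780 (SE 0.20 and 0.11, n = 2 arrays per group). The interferon and antigen presentation lists differed between lines in resistance, as did IFI44, an interferon-induced gene that rose in H23 (2.35-fold) and OVCAR3 (2.03-fold) and fell in A2780 (10.1-fold, well above background on 1 of 2 resistant arrays). Between lung and ovarian lines limma called 0 genes for resistance (586 at an unadjusted p under 0.05, smallest adjusted p = 1) and 0 for treatment (1541, smallest adjusted p = 0.43), with 2 lines per tissue. On simulated data for treatment this test recovered 0%, 1.5% and 0% of planted differences of log2 1, 2 and 4, so a count of 0 says little about such differences. With the 24 arrays taken as samples and the slide as a fixed block it called 11733 and 14606, a fit that ignores the spread between lines of a tissue.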

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

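The tests of slides grouped another way, the test of scaling on calls across lines, the tests of the reversal split by line, the tests of slides of the same number and the limit of the splits to those that part all 4 lines were chosen after the results were seen.

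The measured resistance changes differed between the lines. The interaction test called 12400 genes for resistance and 17262 for treatment, and 1126 and 1918 of these were called higher in 1 line and lower in another. In A2780 the resistance change of interferon response genes lay below the mean of the other lines, by a median log2 of -2.17 (camera adjusted p = 1.78e-20, and adjusted p = 0.0176 with an estimated correlation). That of antigen presentation genes did so as well, by -2.40 (adjusted p = 2.6e-19, and 0.0176 with an estimated correlation). In OVCAR3 antigen presentation genes lay above the mean of the other lines, by 1.24 (adjusted p = 6.04e-16, and 0.0176 with an estimated correlation). With the slide as a fixed block the adjusted p was 2.13e-16, 7.1e-16 and 2.32e-14, and 0.0362, 0.0305 and 0.0305 with an estimated correlation. The mean set against OVCAR3 includes the fall in A2780. Medians of the antigen presentation list were 0.531 in H23, 0.098 in H460, 0.472 in OVCAR3 and -1.675 in A2780, so OVCAR3 did not lie above H23. Each p was adjusted over 128 tests per comparison. These tests take the 2 arrays of a group as replicates. If those are technical, differences between single cultures cannot be separated from differences between lines.

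The first pattern is the 97 genes called the same way for resistance in 3 or more lines, among them C3, CH25H and TMPRSS15. Dim probes alone are argued against, since among genes well above background on all 24 arrays the count was 26, or 7.8 times that of independent lists. Effects of the slides stay open: of genes 2-fold apart in 3 or more lines on slides of 1 number, 27.7% kept their sign on the slides of the other number (31.0% the other way round). A regrouping of the same slides gave 870 genes against 244. It gave 743 in 1 direction and 127 in the other, with an arbitrary sign, against 105 higher and 139 lower. Across lines the real count was 0, which 8 of the 8 splits that part all 4 lines reach whatever the data (highest other 0), so this says nothing about chance. A shared response to cisplatin selection could not be separated from the slides and remains untested.

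The second pattern is the excess of raised over lowered genes after treatment, with cancer-testis genes such as MAEL among the raised ones. For calls in 3 or more lines, scaling alone is argued against, since 63.6% were raised in the scaling least in favour of it, while for calls across lines it is not excluded, since the share raised was 36.4% with quantile normalization. That share was 42.6% among genes well above background on all 24 arrays. This filter drops genes silent before treatment, so the 42.6% does not bear on scaling. The switching on of genes silent before treatment may contribute: 29.3%, 31.6%, 32.0% and 29.5% of raised genes in H23, H460, OVCAR3 and A2780 were not measured above background before it, against 4.9%, 14.4%, 4.4% and 5.5% of lowered genes after it, a difference of at least 17.2 percentage points. Of the calls measured on both sides 56.7%, 62.8%, 64.2% and 60.7% were raised in the main scaling. Detection on both sides depends on the change itself, so these shares cannot say how much switching on contributed. For the 2708 genes across lines, the 8 splits that part all 4 lines are too few for a share under 0.05 (1 gave as many, highest other 0). Regrouping the slides gave at most 128 genes higher and 758 lower, and since the sign of a regrouping is arbitrary, 758 bears on both directions. Slide effects of the size seen between slides of 1 condition are argued against for the genes raised in 3 or more lines (758 against 3384). They are not for the lowered ones (758 against 695), and a difference common to both slides of a condition stays open.

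The third pattern is that genes lowered in resistant cells, such as KCNJ8 and LAYN, were raised after treatment. Their low level in resistant cells is argued against as the whole cause, since the count was at least 2.02 times that of uncalled genes of the same level. With separate resistant arrays for the 2 comparisons the covariance was at most -0.148 in H23, OVCAR3 and A2780, which argues against shared arrays alone in these lines, while in H460, at -0.029, the effect cannot be told apart from them. With no shared slide number, the covariance was -0.372 in A2780, which argues against slides of the same number there, the lower of H23 and OVCAR3 was -0.089, which leaves them open, and H460 was at 0.091, where such slides could account for the pattern. Slide differences between conditions stay open, and no biological explanation was tested.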

How the results depend on the processing

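Normexp on the median signal, its fit without spots far under their background, crossed pairing and calls limited to genes measured in a compared group were chosen after the data were examined. Values below are given in the order H23, H460, OVCAR3 and A2780, and except where the construction shows it, the cause was not tested.

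Quantile normalization, the authors' deposited table, the mean of all probes and no filter on dim probes (31937 features) kept all 20 counts within 1.5 times. So did the slide as a random block in 8 counts, a trended and robust variance in 10, an added minimum fold in 6 and calls limited to genes measured in a compared group in 8. These counts sum both directions. Of the calls across lines after treatment, the share higher fell from 69.9% to 36.4% with quantile normalization, and likewise in the authors' deposited table. With a filter for all 24 arrays, which tests 18418 features, genes called for resistance were 2241, 102, 988 and 1728 and for treatment 5242, 2552, 2397 and 5238, calls in 3 or more lines 26 and 1237, raised then lowered 685, lowered then raised 1086, and across lines after treatment 1465. Without a minimum fold they were 9688, 567, 5313 and 7734 for resistance and 14649, 10495, 10797 and 15266 for treatment, 397 and 7196 in 3 or more lines, 4928 raised then lowered and 5790 lowered then raised.

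With normexp on all spots, 1 to 10 spots on 7 arrays moved the fitted background mean to as low as -1626.4, against -10.1 to 0.2 without spots more than 20 under their background, so the counts of the first fit come from those spots in part. It gave 1165, 4, 331 and 815 genes for resistance and 3797, 788, 1245 and 4176 for treatment, 5 and 488 in 3 or more lines, 351 raised then lowered, 480 lowered then raised, 79 across lines after treatment, and 2358 and 5791 that differed between lines. The second fit gave 2009, 131, 1403 and 1885 for resistance, 5891, 2926 and 3351 for treatment in the first 3 lines, 16 and 1578 in 3 or more lines, and 1047 lowered then raised. The 10 named genes lowest across lines after treatment, NUPR1 among them (limma adjusted p = 0.111), no longer passed in the first fit, and NUPR1 did not in the second (limma adjusted p = 0.0524).

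Arrays of 1 number were also tested alone. Across lines, number 1 alone gave 661 genes for resistance and 4196 for treatment, and number 2 alone 487 for resistance. With line by number as the block over 24 arrays, 12 and 9393 passed. With the replicate number as a block, counts within lines were 3777, 255, 2304 and 3649 for resistance and 9147, 5225, 5537 and 9834 for treatment, and it moved no count by over 1.5 times. Deviations of the same number in a line correlated with r of -0.177 to -0.077 between sensitive and resistant arrays, -0.333 to -0.286 between resistant and treated, and 0.395 to 0.533 between sensitive and treated arrays, and arrays of different lines gave -0.204 to 0.002, -0.362 to -0.259 and 0.319 to 0.551, so the numbers were not taken to pair the samples. Crossed pairing gave 4027, 273, 2370 and 3779 for resistance and 9475, 5388, 5713 and 10020 for treatment.

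With the slide as a random block over 24 arrays, 2283 genes passed across lines for resistance and 13438 for treatment, a fit without the spread between lines. The slide as a fixed block over 24 arrays gave 11733 and 14606 between lung and ovarian lines. Without a line block 512 passed across lines after treatment. Without H23, H460, OVCAR3 or A2780 the count was 1091, 1105, 749 or 699, with fewer values in the fit.

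Leaving out 1 array at a time, where the lone array of a group is taken to vary like the others, genes for resistance ranged from 3359 to 3708, 237 to 580, 1797 to 2075 and 3142 to 4325, and for treatment from 8470 to 8654, 4745 to 4864, 4744 to 5051 and 9052 to 9338. The 580 came without replicate 2 of sensitive H460. Calls in 3 or more lines ranged from 83 to 117 and 3011 to 3147, raised then lowered from 1026 to 1152, lowered then raised from 2526 to 3419, across lines from 0 to 0 and 699 to 2813, with the left-out lines counted in, and genes that differed between lines from 11221 to 12654 and 16392 to 16711.

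Among named genes, the resistance change turned sign for APOA4 (log2 -0.161) and HNRNPK (0.017) with the mean of all probes and for ADGRF3 (-0.018) with the filter for all 24 arrays. The treatment change turned sign for MAPKAPK2 with the mean of all probes (0.236) and with quantile normalization (0.001). Of the lists, 6 passed for resistance in the reported setting and 10 with normexp on all spots. After treatment 8 passed as higher and 1 as lower, against 13 and 0 with quantile normalization and in the authors' deposited table, and 12 and 0 with the filter for all 24 arrays. Signal over background limits dim genes most.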

Other observations

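The correlations between lines without shared slides were chosen after the data were examined.

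Several genes with known roles in differentiation and stress changed in some of the lines on becoming resistant, and ALDH1A3 and SLC7A11 did so in opposite ways. ALDH1A3, an aldehyde dehydrogenase gene used as a stem cell marker, rose in H23 (log2 3.07 ± 0.14, n = 2 arrays per group) and A2780 (3.45 ± 0.14) and fell in OVCAR3 (at least 5.77-fold). LIN28B, an inhibitor of let-7 maturation, fell in H23 (at least 6.04-fold) and OVCAR3 (at least 11.9-fold). SLC7A11, the cystine transporter gene, fell in H23 (log2 -2.08 ± 0.12) and rose in A2780 (2.14 ± 0.12). IRS2, an insulin receptor substrate gene and a published miR-7 target, rose in H23, OVCAR3 and A2780 (log2 3.18, 2.33 and 1.08, SE 0.17), and GDF15, a stress cytokine gene, rose in H23 and OVCAR3 (log2 2.43 and 1.79, SE 0.17). The cytokine gene IL6 rose in H460 and OVCAR3 (log2 1.48 and 1.69, SE 0.30) and in A2780 (at least 1.57-fold), with log2 0.73 in H23 (limma adjusted p = 0.0733). The TGF-beta antagonist gene BAMBI rose in H23 and A2780 (log2 3.75 and 2.93, SE 0.19).

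After treatment the aldo-keto reductase genes AKR1C1, AKR1C3 and AKR1B10 rose in H23 (log2 6.87, log2 6.88 and at least 14.2-fold) and A2780 (log2 4.07, 4.46 and 3.50), while in H460 AKR1C1 and AKR1B10 were at -0.65 and -0.24. HLA-DRA rose in H23 (at least 7.65-fold) and A2780 (at least 14.9-fold) and fell in OVCAR3 (log2 -1.35 ± 0.47), the line in which it had risen with resistance. ERAP2, an antigen-trimming peptidase gene, fell in H23, OVCAR3 and A2780 (log2 -2.89, -1.01 and -2.82, SE 0.14), and its mean over lines did not pass (limma adjusted p = 0.0605). CCNE2, a cyclin gene, had a mean of log2 1.51 ± 0.40 (adjusted p = 0.0504).

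Across genes, which are not independent replicates, the changes of resistance correlated between pairs of lines with r from -0.047 to 0.118, and from -0.207 to -0.132 without shared slides. With shared slides r was 0.093 to 0.313, so the sign depended on the slides and does not show that the lines changed in opposite ways. For treatment r ranged from 0.357 to 0.545, from 0.226 to 0.439 without shared slides, and from 0.396 to 0.553 with them. These are 6 pairs of 4 lines for each comparison.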
